A study of artificial sequences and marine sediment metagenome with 11 samples.

How the data were processed

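Sediment was sampled at 2 stations of the Western English Channel, L4 (50° 13.30 N, 4° 11.40 W) and Rame Head (50° 17.75 N, 4° 16.00 W), in July 2008 and March 2009. The gene amoA, which encodes subunit A of ammonia monooxygenase, was amplified by PCR with bacterial or archaeal primers and hybridised to microarrays of 70-nucleotide probes, each standing for an archetype, that is a group of related sequences within 15% of the probe. Per the labels' protocols, 1000 ng of Cy3-labelled target was hybridised together with 0.25 pmol of a Cy5-labelled 20-nucleotide standard that binds a stretch carried by every printed probe, and the signal was defined as the Cy3 to Cy5 ratio.

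The deposited files hold spot intensity values for each channel on a linear scale, written by GenePix Pro 6.0 with no normalization, per the file headers. Foreground and local background medians and the background SD were read for both channels. The first image of every file was the red (Cy5) scan and the second the green (Cy3) scan, per the file headers, including 1 file (Rame Head, July 2008, bacterial) whose columns carried other channel names. The depth of a sample does not apply to arrays, and the number of arrays limits the precision.

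There were 7 bacterial arrays and 4 archaeal arrays. Bacterial arrays were grouped by site and month from the sample titles, with 2 arrays per group and 1 for Rame Head in July. The array titled Rame Head March 2009 B carried a location label of July 2008. It was placed by its title, and both other treatments of it were run. Duplicate arrays came from duplicate targets of 1 sediment sample per site and month, so p-values measure only the spread between arrays, which may be technical. Each bacterial group lay on a slide of its own, so slide and group cannot be told apart. The archaeal arrays shared 1 slide.

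Spots marked bad or not found were left out, as were spots whose Cy5 foreground did not exceed the background median by 2 background SDs. This condition on Cy5 was not part of the design fixed before the data were examined. It was set before any comparison was computed. Without it 2 bacterial archetypes passed for month, against 0 with it. Intensities were corrected with the normexp method of limma 3.58.1 (offset 50) in R 4.3.3, log2(Cy3/Cy5) was averaged over the spots of an archetype, and each array was centred on the median of its amoA archetypes. The design text gives 3 replicate probes per archetype, whereas the files held 8 spots per bacterial archetype and mostly 4 per archaeal probe. The name of archetype A18 was spelled in 2 ways, which were merged. The bacterial arrays held 28 amoA archetypes and 42 probes of other genes. On the archaeal arrays the files do not annotate the gene of a probe, and the 30 probes named as a clone with a sequence accession and without the NIR prefix were taken as the amoA probes. The remaining 441 probes were treated as other genes.

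An archetype was detected on an array where at least 2 of 3 of its spots had a Cy3 foreground above the background median plus 2 background SDs, and it was tested where detected on at least 2 arrays. Bacterial contrasts were taken from 1 limma fit with 4 group means over the 7 arrays, so that the lone Rame Head July array was assumed to vary like the others. The spread of an archetype was moderated over the tested archetypes, with 3 residual and 37.4 prior degrees of freedom. Its SE and p therefore reflect mostly the common spread, and less that of its own duplicates. Archaeal contrasts came from an additive site and month model over the 4 arrays, which leaves 1 residual degree of freedom per probe. Benjamini-Hochberg adjustment was made over the tested archetypes, with 0.05 as the threshold. Shares are percentages of the summed Cy3/Cy5 ratio over the amoA archetypes of an array. They are shares of signal, since probes can differ in how well they bind. Differences in community composition were tested with an exact one-sided permutation test of the pseudo-F of Bray-Curtis dissimilarities.

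The archetypes named are those past the threshold in each contrast, up to the 10 highest and 10 lowest, with the 5 of smallest p where fewer than 5 passed, and the 5 largest mean shares at each site and month. Of the fixed lists, bacterial archetypes named for Nitrosomonas (12, read from the letters NM with species or strain names) could be formed. From strain codes, 1 archetype each could be read as Nitrosococcus (A28NOC_C107) and, after its values had been seen, as Nitrosospira (A3NPAV), which is too few for a list. No archaeal probe was annotated by source, so that list was not formed either.

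The fit was tested on simulated data with 6 archetypes changed in each of 100 simulations. The changes had random signs, and the noise was normal, independent and of the same SD for all archetypes, with no slide or sample effect. In the data the site calls shared a sign, as did the interaction calls, and duplicates of some archetypes lay far apart. The simulated rates may therefore not hold for the data. Of changes of 1.0 on the log2 scale, 98.8% were recovered for the site contrast, 42.3% for the interaction and 20.3% for the archaeal site contrast. With centring on the median, the mean share of false calls for a change of 1.5 reached 12.1% for the month contrast over both sites, against 3.33% without centring, because changed archetypes move the median. The alternatives covered background correction, centring, the filter, spot averaging, loess, the tests adjusted for, the replicate letter and slide position as blocks, the slide as a random block, averaged duplicates, the conflicting label and the omission of each array. Loess takes out the trend of the ratio with spot intensity. Both hold Cy3, so loess can also take out the signal of bright archetypes, and a call lost or turned with it may reflect that loss. With adjustment over all probes, the fit and its moderation also ran over the other-gene probes. Averaged duplicates and the random slide block used an additive site and month model, which leaves the interaction in the residual. Cy3 alone, omission of spots at the Cy5 ceiling and 2 other spot rules were added after the data were seen.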

Results

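The potential ammonia oxidisers of 2 coastal sediments were profiled by hybridising amplified amoA to archetype microarrays, to ask which bacterial and archaeal groups were present at each station and month. For bacteria there were 2 arrays each from L4 in July 2008, L4 in March 2009 and Rame Head in March 2009, and 1 from Rame Head in July 2008. For archaea there was 1 array per site and month. Each bacterial array carried 1536 spots, of which 224 belonged to amoA archetypes, and each archaeal array 4608, of which 120 were taken as amoA. The median Cy5 foreground over bacterial amoA spots ranged from 23398 at L4 in March (A) to 48403 at L4 in July (B), and 14 and 18 of these spots reached the scanner ceiling on the L4 July arrays A and B. The bacterial and archaeal arrays were not set against each other.

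Archetypes A1MARINEAOB and A5CBPLUME held the largest shares of the bacterial signal at both sites and in both months. A1 made up 28.9% ± 0.0373 (SD, n = 2) at L4 in July, 23.6% ± 1.51 (SD, n = 2) at L4 in March, 28.1% (n = 1) at Rame Head in July and 32.5% ± 2.09 (SD, n = 2) at Rame Head in March. A5 made up 28.5% ± 0.252, 22.1% ± 0.746, 23.2% and 26.3% ± 1.85 in the same order. Next came A17NM_UREA_CLADE, at 5.65% to 6.74%, and A24NM_HALOPHILUS, at 4.43% to 5.94%. The fifth was A25CT1_2 at L4 in July (2.72% ± 0.0874) and A14SEINERIVER elsewhere, at 4.35% ± 0.184 at L4 in March, 3.77% at Rame Head in July and 3.12% ± 1.29 at Rame Head in March. All 28 archetypes were detected on 6 of the 7 arrays, and 26 on Rame Head March A. A stricter comparison left 6 to 13 archetypes per array above the 95th percentile of the other-gene probes.

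**Figure D1:**
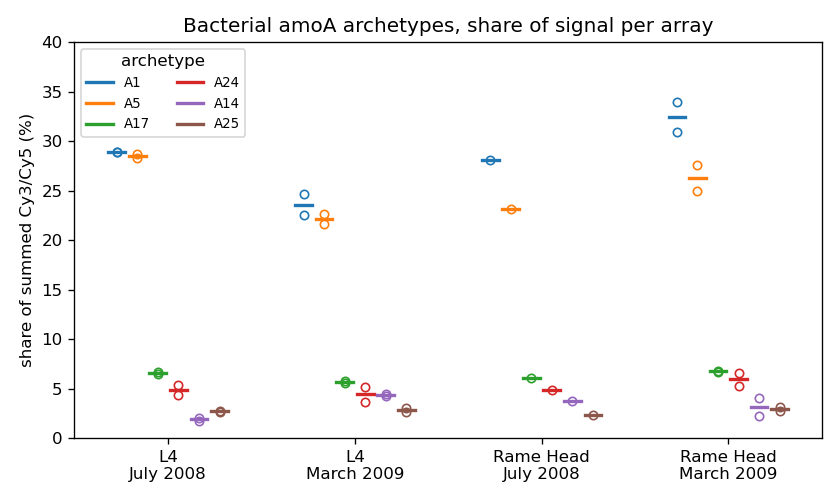
Share of the summed Cy3/Cy5 ratio (percent, vertical axis) of the 6 bacterial archetypes with the largest mean share, by site and month. Circles are single arrays and bars are group means; A1 and A5 lie between 21.6% and 33.9% on every array, and the other 4 below 10%.

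Averaged over both months, 4 bacterial archetypes were higher at Rame Head than at L4, relative to the median archetype. The median archetype itself lay near the median other-gene probe, from -6.47 against -6.33 on L4 March A to -6.28 against -6.90 on L4 July B. Differences from it, here and in the contrasts below, can therefore also reflect specific against nonspecific signal. A8NM_OLIGOTROPHA_CLADE was 1.76-fold higher (log2 difference 0.82, SE 0.19, adjusted p = 0.00322 in limma), but exceeded the 95th percentile of other-gene probes on only 4 of the 7 arrays. A14SEINERIVER was 1.45-fold higher (0.54, SE 0.18), A24NM_HALOPHILUS 1.45-fold (0.53, SE 0.17) and A1MARINEAOB 1.44-fold (0.52, SE 0.16), each with an adjusted p of 0.0279. A8 and A14 had higher group means at Rame Head in both months. The Rame Head March duplicates of A14 read 2.09 (A) and 1.17 (B), and those of A8 lay further apart. The SE of both, mostly shared across archetypes, understates their own spread. A1 and A24 were lower there in July (4.25 against 4.46 and 1.73 against 1.89, centred log2 ratio) and higher in March (5.07 against 3.82 and 2.61 against 1.39). A17NM_UREA_CLADE did not pass (0.38, SE 0.16, adjusted p = 0.101). No archetype was lower, and 5 of the 28 had an unadjusted p under 0.05. The count was 0 when duplicate arrays were averaged to 1 value per sediment sample and when the slide was a random block. Both used an additive model that leaves the interaction in the residual. The count was also 0 with the replicate letter or the slide position as a block, with plain background subtraction, with no centring and when fitted and adjusted over all probes. Without Rame Head March A none of the 4 passed, with A8 at 0.50 and A14 at 0.31, and the duplicates there read 2.05 (A) and 0.78 (B) for A8. Without L4 March B none passed either (A24 at 0.33), and without L4 July A, L4 March A or L4 July B 1, 2 and 3 of the 4 did. With loess none of the 4 passed as higher, A24 passed as lower at Rame Head (-0.43), and A17 passed as higher (0.80). A8 (-0.42) and A1 (-0.10) turned negative with loess, and A14 read 0.48. When arrays were scaled to their summed signal, which moved the median difference from 0.06 to -0.25, 0 archetypes were higher and 8 were lower at Rame Head.

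Between the months, no bacterial archetype passed the threshold in limma, and 5 of 28 had an unadjusted p under 0.05. The 5 with the smallest p were A14SEINERIVER (March minus July 0.56, SE 0.18) and A22NM33 (0.47, SE 0.15), both with an adjusted p of 0.0602, A8NM_OLIGOTROPHA_CLADE (0.49, SE 0.19) and A4CBSED (-0.42, SE 0.16), both at 0.0966, and A25CT1_2 (0.34, SE 0.16, adjusted p = 0.248). The count was 2 without the array whose labels conflict, 2 with it placed in July, and 2 when spots with little Cy5 standard were kept.

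The difference between months itself differed between the sites for 6 bacterial archetypes, all with a higher March minus July difference at Rame Head. They were A5CBPLUME (interaction 1.49 on the log2 scale, SE 0.31, adjusted p = 0.000564 in limma), A1MARINEAOB (1.45, SE 0.32), A24NM_HALOPHILUS (1.38, SE 0.35), A17NM_UREA_CLADE (1.32, SE 0.31), A25CT1_2 (1.22, SE 0.32) and A3NPAV (0.98, SE 0.31, adjusted p = 0.0134). They include the 4 archetypes with the largest shares. Each group was 1 sediment sample on a slide of its own, so these p-values rest on the spread between duplicates of the same sample. The fits with averaged duplicates or a random slide block hold no interaction term, so the interaction has no such check. A25 exceeded the 95th percentile of other-gene probes on 6 of the 7 arrays and A3 on only 3. The number of calls depended on how the array of Rame Head March 2009 B, a March sample by its title, was placed. With it in July the 6 interactions stayed positive, within a factor of 1.5 of the values above. With that array placed in July, after its location label, 0 archetypes passed, and without it 7 did, 6 positive and 1 negative. Without Rame Head March A 9 passed, 6 positive and 3 negative, and centred on the median of all probes 11 did, all positive. Scaled to the summed signal, which moved the median interaction from -0.12 to -1.07, 2 archetypes had a positive and 18 a negative interaction, against 6 and 0. With no centring 1 was positive and 7 were negative. With loess 1 of the 6 passed, A17 (2.24), and the values of A5 (-0.19), A24 (-0.0219) and A25 (-0.16) turned negative, with A1 at 0.03 and A3 at 0.23. Loess can also take out the signal of bright archetypes such as A1 and A5. Whether it did so was not tested, and A17, the next in share, rose while the dimmer A25 and A3 fell. The loess values therefore neither decide on the interaction nor can be set aside. Fitted and adjusted over all probes 3 passed. Without L4 July A, L4 July B or L4 March B 5 of the 6 passed.

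**Figure D2:**
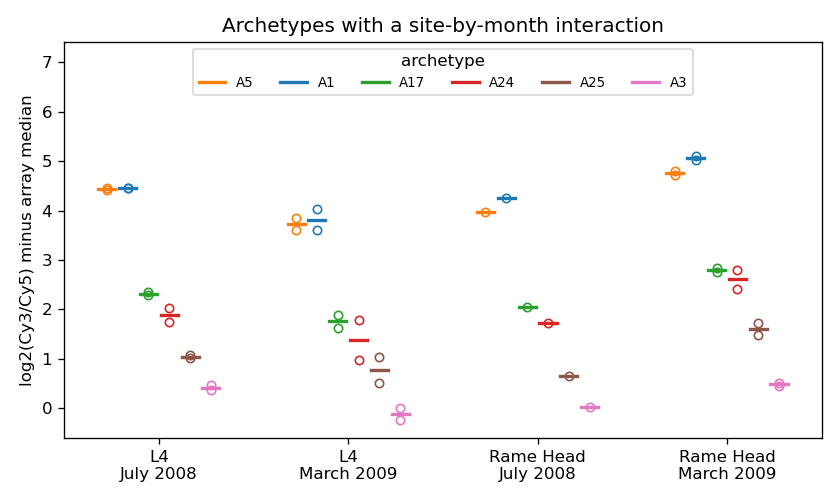
log2(Cy3/Cy5) minus the array median (vertical axis) of the 6 archetypes with a site-by-month interaction. Circles are single arrays and bars are group means; A1 and A5 were lower in March than in July at L4 and higher in March at Rame Head, where July has 1 array.

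Within L4, 3 bacterial archetypes rose from July to March and 4 fell. A14SEINERIVER rose 1.81-fold (log2 difference 0.85, SE 0.22, adjusted p = 0.0114 in limma) and A8NM_OLIGOTROPHA_CLADE 1.67-fold (0.74, SE 0.24). A14 exceeded the 95th percentile of other-gene probes on 6 of the 7 arrays and A8 on 4. A28NOC_C107, the Nitrosococcus archetype, passed as well (0.65, SE 0.21), but it exceeded the 95th percentile of other-gene probes on 0 of the 7 arrays, and without L4 July A its difference was 0.36 and did not pass. A5CBPLUME fell by 0.71 on the log2 scale (SE 0.20, adjusted p = 0.0116), A1MARINEAOB by 0.64 (SE 0.20), A17NM_UREA_CLADE by 0.56 (SE 0.20) and A3NPAV by 0.53 (SE 0.20). A3 exceeded that percentile on only 3 of the 7 arrays. The count was 0 with the replicate letter or the slide position as a block, with plain subtraction, with no centring and when adjusted over all probes. With the conflicting array in July 1 passed (A14). With loess 2 of the 7 passed, A14 and A17, while A8 (-0.10) and A5 (0.15) turned and A1 stood at -0.01. None of the 7 passed without L4 July A or without L4 March B (A1 at -0.42), 2 did without L4 July B and 4 without L4 March A. Centred on the median of all probes 0 rose and 8 fell, with A14 at 0.56, A8 at 0.44 and A28 at 0.35 no longer passing, and with no background subtraction 0 rose and 3 fell. Scaled to the summed signal, 17 rose and 1 fell.

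Within Rame Head, 7 archetypes rose from July to March and 1 fell, with 1 array in July. A25CT1_2 rose 1.93-fold (0.95, SE 0.25, adjusted p = 0.0128 in limma), A24NM_HALOPHILUS 1.84-fold (0.88, SE 0.27), A1MARINEAOB 1.76-fold (0.81, SE 0.24), A5CBPLUME 1.73-fold (0.79, SE 0.24) and A17NM_UREA_CLADE 1.69-fold (0.76, SE 0.24). A22NM33 rose 1.64-fold and A18PLUSSEE 1.57-fold, but they exceeded the 95th percentile of other-gene probes on only 2 and 3 of the 7 arrays. A4CBSED fell by 0.83 (SE 0.25, adjusted p = 0.0128), but it exceeded the 95th percentile of other-gene probes on 0 of the 7 arrays. The count was 0 with the slide position as a block, with no centring and when adjusted over all probes. It was 1 with the conflicting array in July, none of the 8 (A4 at -0.0393), and 3 without it, 2 of them among the 8 (A4 at -0.58, not passing). Without Rame Head March A 4 of the 8 passed, without L4 July A or L4 July B 6 did, and with loess 1 did (A17). Scaled to the summed signal 0 rose and 10 fell. With the conflicting array in July the 7 rises stood at 0.32 (A5) to 0.72 (A24), and without it at 0.67 (A18) to 1.07 (A25). With loess A5 (-0.04), A22 (-0.11) and A18 (-0.38) turned negative.

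Of the 12 archetypes named for Nitrosomonas, a genus of ammonia-oxidising bacteria, 2 were higher at Rame Head as an average over the months (A8 and A24, the latter in March and not in July) and 10 did not pass. Adjusted over the list alone, 2 were higher. For the interaction 2 were positive (A17 and A24) and 10 did not pass, with the same count adjusted over the list alone. Within L4, 1 rose (A8) and 1 fell (A17). Within Rame Head, 3 rose (A17, A22 and A24). For the months over both sites none passed, 0 also when adjusted over the list alone. As a set the list did not move apart from the other archetypes in any of the 5 contrasts (camera, smallest p = 0.708 with a preset correlation and 0.827 with an estimated correlation). The median over the list for the interaction was -0.21 and its mean 0.11.

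The bacterial profiles of duplicate arrays differed by 3.21% to 6.55% in Bray-Curtis dissimilarity, those of the 2 months at a site by 9.01% to 15.0%, and those of the 2 sites in a month by 8.22% to 19.0%. Arrays that differed in both site and month were 5.76% to 9.86% apart. Only duplicates shared a slide and a sediment sample, so their smaller distances may reflect either. Neither site (exact one-sided permutation p = 0.229) nor month (exact one-sided permutation p = 0.543) separated the 7 arrays. The 35 splits allow a p of 0.0286 at the smallest. These tests count duplicate arrays as separate, and the interaction was not tested on the profiles.

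On the archaeal arrays 23 of 30 amoA probes were detected at L4 in July, 23 at L4 in March, 24 at Rame Head in July and 15 at Rame Head in March. On the last array 22.4% of the amoA spots had a Cy3 foreground below their local background, against 1.72% to 3.45% on the others. AJ41_4 held the largest share of the amoA signal on each array, at 14.0%, 12.9%, 13.0% and 14.3% in that order. R60_70_278 held 10.6% to 12.8% and HF770_22G04 10.02% to 10.8%. TOB_44 held 8.43% at L4 in July, 11.2% at L4 in March and 9.51% at Rame Head in July. The fifth place was held by JCS82_4 at L4 in July (6.12%) and Rame Head in March (7.46%), and by S33_A_12 at L4 in March (7.43%) and Rame Head in July (8.26%). At Rame Head in March AOAB_SH04 stood second at 10.9%, but it was detected on 0 arrays and its spots there carried little Cy5 standard, so that share has no firm basis. No amoA probe exceeded the 95th percentile of the other-gene probes on any of the 4 arrays.

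**Figure D3:**
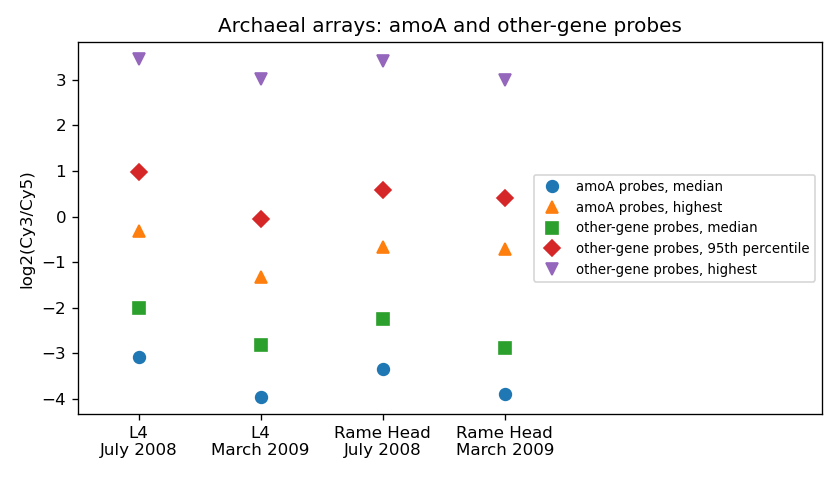
log2(Cy3/Cy5) on the 4 archaeal arrays (vertical axis), with the median and highest of the amoA probes and the median, 95th percentile and highest of the other-gene probes. The highest amoA probe lies below the 95th percentile of the other-gene probes on each array.

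No archaeal amoA probe differed between sites or months past the threshold in limma, among 24 tested. At an unadjusted p under 0.05 there were 3 for site and 1 for month. The 5 probes of smallest p for site were HB_29 (Rame Head minus L4 1.39, SE 0.34, adjusted p = 0.144), EF500_19O12 (1.11, SE 0.38), TOB_159 (-1.07, SE 0.40), JCS82_4 (0.66, SE 0.36) and DS4_20 (-0.49, SE 0.35). For month they were HB_29 (March minus July 0.88, SE 0.34, adjusted p = 0.833), TOB_61 (-0.61, SE 0.34), EF500_19O12 (0.54, SE 0.38), MG85_37 (-0.56, SE 0.43) and BS80E_D4 (0.56, SE 0.43). The median 95% confidence interval reached 0.88 to either side. In the simulated data for site 20.3% of changes of 1.0 and 54.7% of changes of 1.5 were recovered, so that changes of those sizes were often missed. The median amoA probe lay below the median other-gene probe on each array (log2 ratio). It read -3.08 against -1.99 at L4 in July and -3.96 against -2.81 at L4 in March. At Rame Head it read -3.33 against -2.25 in July and -3.89 against -2.89 in March. Both the differences and their absence can therefore reflect nonspecific signal. With a stricter spot rule chosen after the data were seen, 1 probe passed for site.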

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

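All tests of explanations in this part but that of the Cy5 standard on other-gene probes were chosen after the results they bear on had been seen.

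The March minus July difference differed between the sites for A5CBPLUME (1.49), A1MARINEAOB (1.45), A24NM_HALOPHILUS (1.38), A17NM_UREA_CLADE (1.32), A25CT1_2 (1.22) and A3NPAV (0.98), by the test of the interaction. The tables argue against the Cy5 ceiling on the L4 July arrays as its source, since all 6 passed both with those spots left out and with Cy3 alone. A shift of the whole array in specific against nonspecific signal cannot be told apart from a difference between archetypes: the archetypes more than 1 log2 unit above the median other-gene probe on every array were 4 of these 6 and no others, so that a test of heterogeneity among them (exact permutation p = 0.721) decides nothing, since all 4 had been called for the same rise, A16KYSINGFJORD, chosen after its values were seen, read -0.77 (SE 0.92) with that level subtracted and left the 5 archetypes over the 95th percentile at an exact permutation p of 0.073, and A25 and A3 lay too near that level (lowest value -0.14); 7 arrays give such tests little power. A wrong month for the array with conflicting labels stays open as well. That array lay nearer the other Rame Head March array (0.346) than the July array (0.478), but it shares a slide with the former. Slide and month therefore cannot be told apart for it. Each group was 1 sediment sample on a slide of its own, so a difference between slides or samples stays open for the whole interaction. A biological difference between sites and months stays open and untested.

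For the site contrast, 3 of the 30 splits of the 7 arrays that keep all 4 groups filled, the real one included, gave at least the 4 calls observed, and the highest other split gave 6, so chance was not excluded. For the month contrast the count was 0, which all 30 splits reach, so they say nothing about chance there; the highest other split gave 6. In both cases the split with 6 calls set L4 July and Rame Head March against L4 March and Rame Head July, which is the interaction. In a fit of 2 groups without the other factor, both real splits gave 0 calls and the highest other split 4.

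Other-gene probes exceeded the highest archaeal amoA probe 72 times at L4 in July, 74 times at L4 in March, 72 times at Rame Head in July and 52 times at Rame Head in March. These probes lie outside the comparisons. Spots with no probe carried at most 0.00717 of the median net Cy3 of all other-gene probes. Such spots read near 0 once their own background is subtracted, so this check does not decide on background left over after subtraction. Little Cy5 standard does not account for most of the brighter probes, since 62.5% or more still exceeded the brightest amoA probe on net Cy3 alone. The order of all other-gene probes was alike on the 4 arrays (lowest Spearman correlation 0.932, across probes). Cross-hybridisation of the amoA product and another labelled target shared by the samples would both give this, so the pair cannot be told apart. Which probes are amoA was read from their names, so a wrong assignment of the brighter probes was not excluded either. Of the brighter probes 25, 28, 29 and 10 carried the NIR prefix, in the order of arrays above. No biological explanation was tested.

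The control probe PSTUTZ14405 gave a log2 ratio of at least 2.20 on the bacterial arrays, against at most -7.16 for spots with the standard alone.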

How the results depend on the processing

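Settings added after the data were seen were Cy3 alone, omission of Cy5 ceiling spots and the 2 other spot rules. Causes were not tested unless stated. Counts are archetypes past the threshold. For the site contrast (4) they were 0 with plain subtraction, no centring, adjustment over all probes, the replicate block, the position block, averaged duplicates and the slide as a random block, 1 with no subtraction, 2 with loess (1 higher, 1 lower) and 2 with the median of all probes. For month (0) they were 1 with plain subtraction, 2 with flagged spots alone left out, 3 without ceiling spots, and 2 with the conflicting array left out or in July. For the interaction (6) they were 3 adjusted over all probes, 1 with loess, 11 with the median of all probes, 0 with the conflicting array in July and 7 with the replicate block. For month at L4 (7) they were 0 with plain subtraction, no centring, adjustment over all probes and either block, 3 with no subtraction and 2 with loess. For month at Rame Head (8) they were 0 with no centring, adjustment over all probes and the position block, 1 with loess, 1 with the conflicting array in July and 3 with it left out. The balance of directions turned with scaling to the sum for site (8 calls), interaction (20), month at L4 (18) and month at Rame Head (10), with no centring for the interaction (8, of which 7 negative), and for month at L4 with the conflicting array in July (1) and with flagged spots alone left out (7).

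Without each array in turn the counts ranged from 0 to 4 for site, 0 to 2 for month, 5 to 9 for the interaction, 0 to 8 for month at L4 and 3 to 8 for month at Rame Head. The site count was 0 without Rame Head March A and without L4 March B, and month at L4 was 0 without L4 July A and without L4 March B and 2, both rises, without L4 July B. Without the Rame Head July array only month at L4 could be fitted. For the archaeal contrasts no array could be left out, since no residual degrees of freedom remain. The permutation p of composition kept its side of the threshold under all settings, from 0.133 to 0.467 by site and 0.3 to 0.8 by month without each array, where 10 or 15 splits cannot reach 0.05. The replicate letters did not pair the samples: the A arrays' deviations correlated at -0.172, -0.162 and 0.175 between groups.

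The archaeal counts (0) were 2 for site and 1 for month with amoA probes tested whether or not detected, and 1 for site with the strict spot rule. Against the 95th percentile of other-gene probes, the median number detected was 8 of 28 bacterial archetypes and 0 archaeal probes. Of 100 checks of a named bacterial share under another setting, 20 moved by more than the pooled SD between duplicate arrays. With loess the sign turned for site in A8 (-0.42), A24 (-0.43) and A1 (-0.10), for month in A8 (-0.14), for the interaction in A5 (-0.19), A24 (-0.0219) and A25 (-0.16), at L4 in A8 (-0.10) and A5 (0.15), and at Rame Head in A5 (-0.0418), A22 (-0.11) and A18 (-0.38). For archaeal month it turned in BS80E_D4 with plain subtraction (-2.03) and with no centring (-0.16) and in EF500_19O12 with no centring (-0.18). Signal over background limits the dim archetypes, since 15 to 22 of the 28 lay at the level of other-gene probes on each array.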

Other observations

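The comparison and its test in this part were chosen after the data were seen. A1MARINEAOB stood higher relative to A5CBPLUME at Rame Head, with a log2 difference of 0.29 ± 0.016 (SD, n = 3 arrays), than at L4, with 0.06 ± 0.090 (SD, n = 4 arrays), and the ranges did not overlap (0.28 to 0.31 against -0.01 to 0.19). Ranges that do not overlap fix the exact one-sided permutation p at 0.0286, the smallest that 35 splits allow, so this p restates them, and it counts duplicate arrays as separate; over the 4 sediment samples the exact p was 0.167, the smallest those allow. With loess the order turned, at -0.10 ± 0.052 (SD, n = 3 arrays) at Rame Head and -0.02 ± 0.15 (SD, n = 4 arrays) at L4. Loess can also take out the signal of these bright archetypes, so this turn may reflect that loss. Sites cannot be told apart from samples and slides here.

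The effective number of bacterial archetypes, the exponential of the Shannon index of the shares, was 10.7 and 10.6 on the L4 July arrays, 14.6 and 15.2 at L4 in March, 12.7 at Rame Head in July, and 10.3 and 9.21 at Rame Head in March. The shares run over all 28 archetypes, of which only 6 to 13 per array exceeded the 95th percentile of other-gene probes. The number therefore also follows the level of nonspecific signal and does not measure diversity alone.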
